A study of Arabidopsis thaliana with 2 samples.

How the data were processed

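Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antiserum to LHY, a MYB-type transcription factor of the circadian clock, on Arabidopsis thaliana Col-0 seedlings collected 2 h after dawn at an age of 2 weeks, per the labels' protocols. Tissue was cross-linked in 1% formaldehyde for 10 min and chromatin was sheared to fragments of 100 to 1000 bp, per the labels' protocols. DNA from 4 independent ChIP samples was pooled into 1 library, and 1 library of input DNA served as the control, per the labels' protocols. No group had replicate libraries.

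Per the submitters' processing notes, Bowtie and MACS2 2.0.10.09132012 were used with the TAIR9 build; the version of Bowtie, the treatment of reads that match several places and the threshold of the peak caller are not given in the sources used here. The deposited table lists genes rather than intervals. For each gene the authors give up to 4 peaks, each with a −log10 q value from the peak caller and a position in bp relative to the transcription start site (TSS), per the file headers. Another header line calls the same values −log10 of the p-value; they are used here to describe and rank peaks within the list, and in a test of repeated values in the closing section. Per the file headers, the authors paired each peak with the closest gene facing away from it, which places most peaks upstream of a gene by construction. Which point of a peak the position refers to is not given in the sources used here. The phase of expression in constant light, in whole hours after subjective dawn, was taken by the authors from the Diurnal database with a cut-off of 0.8, per the file headers, and was not measured in this series. A gene with a phase is called rhythmic here. A gene without one was counted as not rhythmic, and genes under the cut-off were not told apart from genes absent from the database. The authors' deposited table ends with a count of 610 rhythmic genes of 1602, and the same numbers were obtained by counting its lines. Read depth, pileup, fold enrichment and genome coordinates were not analysed here, so depth is unknown, and no interval below covers variation between chromatin preparations.

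Locus identifiers were matched to a table of TAIR10.1 genes, which was used for symbols, gene biotypes and the order of neighbouring genes; no coordinate from it was used. Of the 1602 loci, 1596 matched. Peaks with the same −log10 q listed under genes at most 5 places apart were counted as 1 shared peak. The promoter window ran from 1000 bp upstream to 200 bp downstream of the TSS. Before the data were examined, 16 gene lists with 308 members were fixed. The 300 members whose symbol and locus went together in the reference table were used, and 8 were left out: RVE6, RVE3, RVE5, COR28, DVR, CDF5, ACO3 and TIP41L. Each list was compared with all other nuclear protein-coding genes (27444 in all) by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 16 lists and a threshold of 0.05. This procedure was tried on 100 simulated sets of bound genes among the 27444, with an odds ratio of 8 for 4 of the lists. It called the smallest of those 4 lists in 44% and the largest in 91% of simulations. The 12 unchanged lists were called in 0.333%. Simulated genes were bound independently, so tandem and duplicated genes were not modelled. An odds ratio of 8 also exceeds those found below for the ABA signalling, light signalling and Aux/IAA lists.

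Several planned tests could not be run because they need sequence or coordinates: a circular-shift test of peaks in promoters, and all tests of the evening element and other motifs. The share of peaks in promoters is therefore given without a test. The rule for named genes, fixed before the data were examined, took the genes at the peaks with the highest fold enrichment and the 10 highest −log10 q values, up to 8 bound members of each list by fold enrichment, all clock list members, and LHY and CCA1. Because fold enrichment was not analysed here, −log10 q replaced it.

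The comparisons of rhythmicity, phase and position with peak strength were chosen after the data had been looked at, as were the window of 6 to 11 h and its 2 alternatives. For these, genes were divided at the quartiles of the −log10 q of their strongest peak, and the strongest group was compared with the weakest by a two-sided Fisher's exact test, adjusted over 4 comparisons by the Benjamini-Hochberg method. Within a subset of genes, the groups were divided anew at the quartiles of that subset, and as an alternative the groups of all genes were kept. Shares have exact Clopper-Pearson intervals and odds ratios exact conditional intervals, both at 95%; they treat genes as independent, although neighbouring and duplicated genes are not. Alternatives covered the promoter window, the background genes, the pairing of peaks with genes, peak strength, biotype, and the removal of list genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.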

Results

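Binding of LHY across the genome of Arabidopsis seedlings was measured in 1 pooled ChIP-seq library against 1 input library, at 2 h after dawn, the time of day at which LHY is most abundant per the labels. The peak list held 1602 genes and 1762 pairs of a gene and a peak. By the rule of equal −log10 q given above, these came from 1712 distinct peaks, of which 50 were shared by neighbouring genes. Equal values also recur at distant genes, so separate neighbouring peaks may have been counted as shared by coincidence. One peak was listed for 1456 genes, 2 for 133, 3 for 12 and 4 for 1. Of the matched loci, 1477 were protein-coding, 69 were pseudogenes, a further 16 were transcribed pseudogenes and 13 were tRNA genes. The −log10 q of the strongest peak per gene had a median of 10.3, with quartiles of 6.80 and 18.3. A number in parentheses after a gene name below is the −log10 q of its strongest peak, given by the authors. Depth is unknown, and with 1 library per group the values carry no replicate error.

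The highest −log10 q in the list, 260.1, belonged to FKF1 (AT1G68050), an F-box blue-light receptor that promotes flowering in long days, at −273 bp from the TSS. CBF1 (AT4G25490), a transcription factor that activates cold-response genes, followed with 202 at −772 bp and had a weaker peak of 10.3 at −64 bp. TOC1 (AT5G61380), the pseudo-response regulator that represses the morning genes of the clock, had 182 at −192 bp. GI (AT1G22770), which acts with FKF1 in day-length sensing, had 162 at −861 bp and 66.0 at −33 bp. JMJD5 (AT3G20810), a jumonji-domain gene of the evening clock, had 161 at 37 bp downstream of the TSS.

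The other genes among the 10 highest were AT1G70420, which encodes a protein of unknown function (169 at −957 bp), the chlorophyll-binding protein gene LHCB1.3 (AT1G29930, 158 at −154 bp), and the B-box zinc finger gene BBX8 (AT5G48250, 156 at −267 bp). PORB (AT4G27440), a protochlorophyllide oxidoreductase of chlorophyll synthesis, had 145 at −127 bp. The remaining gene, AT3G46630, of unknown function, had 148 at −267 bp. Its immediate neighbour in the annotation is LUX, a MYB-type component of the evening complex that was itself absent from the list; this was looked up after the values were seen. Sequences of the LHCB1 genes are nearly identical, and how reads matching several copies were treated is not given in the sources used here.

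Most peaks lay close to the TSS of the paired gene, which pairing with the closest gene facing away favours by construction. Of 1633 pairs with protein-coding genes, 1081 (66.2%, 95% exact interval 63.8 to 68.5) lay in the promoter window. Over all pairs the median position was −469.5 bp, and 443 pairs (25.1%) lay within the 200 bp upstream of the TSS, as at TOC1, LHCB1.3 and PORB. At or downstream of the TSS lay 198 pairs (11.2%), and 168 (9.53%) lay more than 3000 bp upstream. No test was made of this share, since the authors' pairing rule itself favours upstream positions; with a window of 500 or 3000 bp upstream the share was 51.2% or 89.8%. The percentage of protein-coding genes with a peak was between 5.20 and 5.60 on each of the 5 chromosomes.

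**Figure D1:**
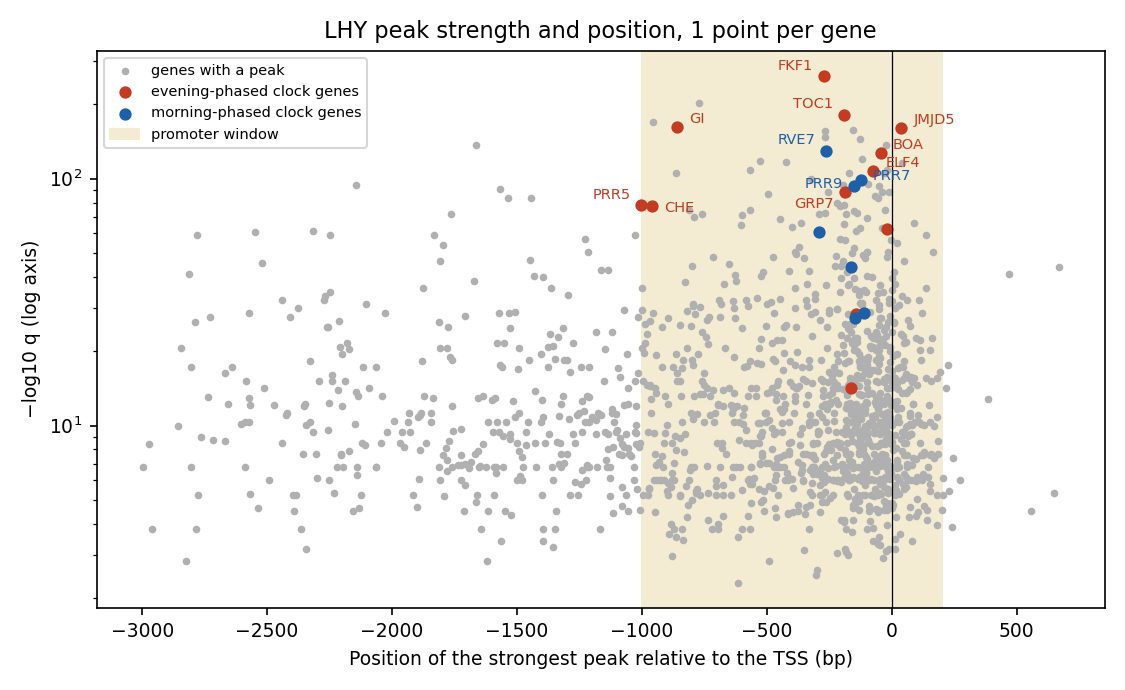
Each point is a gene, at the position of its strongest peak relative to the TSS (x axis, bp) and the −log10 q of that peak (y axis, log scale); clock list members are coloured, the shaded band is the promoter window, and 143 genes with a strongest peak more than 3000 bp upstream, RVE1 among them, are not drawn. Among the coloured genes FKF1, TOC1, GI and JMJD5 are highest, between 161 and 260.1, and the unlabelled grey points among them include CBF1 (202) and AT1G70420 (169); PRR5 lies at −1003 bp, just outside the band.

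Clock genes were bound more often than other genes. Among 15 evening-phased clock genes, 11 had a peak in the promoter window (73.3%, exact interval 44.9 to 92.2), against 3.80% of other protein-coding genes (odds ratio 69.7, 95% interval 20.6 to 300.5, adjusted p = 4.73e-12, Fisher's exact test). Besides FKF1, TOC1, GI and JMJD5 these were BOA, a homologue of LUX (127), ELF4 (107) and ELF3 (62.7), components of the evening complex, the RNA-binding protein genes GRP7 (88.6) and GRP8 (28.3), CHE, a TCP transcription factor that represses CCA1 (77.3), and PRR3 (14.2). The pseudo-response regulator gene PRR5 had 78.0 at −1003 bp and 77.1 at −2255 bp, both outside the window. LUX, ZTL and LKP2 had no peak in the list. The list was named before the phases were seen, and the deposited phases of its bound members ran from 5 h (CHE) through 7 h (GI, PRR5) to 12 h (ELF3, ELF4).

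Of 13 morning-phased clock genes, 7 had a promoter peak (53.8%, odds ratio 29.4, 95% interval 8.46 to 106, adjusted p = 6.68e-07, Fisher's exact test). LHY had a peak at its own promoter, with 28.7 at −110 bp, and CCA1, its closest homologue, had 60.6 at −292 bp. The other bound members were RVE7 (129.9), the pseudo-response regulator genes PRR7 (98.9) and PRR9 (93.1), RVE2 (43.9) and the coactivator gene LNK2 (27.2). RVE1, which links the clock to auxin, had 38.6 at −3309 bp and 8.502 at −1505 bp. The deposited phase was 22 h for LHY, 23 h for CCA1 and RVE1, 1 h for LNK2, 3 h for PRR9 and RVE7 and 6 h for PRR7, but 15 h, in the subjective night, for RVE2. RVE4, RVE8, LNK1, LNK3 and LNK4 had no peak, and RVE3, RVE5 and RVE6, left out of the test, were not in the list either.

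Genes of the list responsive to abscisic acid (ABA) or cold, which mixes both kinds, were bound more often than other genes. Of its 20 members, 10 had a promoter peak (50.0%, odds ratio 25.3, 95% interval 9.43 to 67.9, adjusted p = 6.84e-09, Fisher's exact test). The tandem genes CBF1, CBF2 and CBF3 each had 2 peaks. The strongest at CBF3 (94.6) lay at −2144 bp and at CBF2 (38.6) at −1673 bp, with weaker ones of 15.3 at −123 bp and 30.4 at −85 bp inside the window. Peaks also lay at the cold-induced gene KIN2 (88.6), at COR27, a cold-induced clock regulator (88.4), at CBF4 (28.9), and at COR15B, a chloroplast protein gene of freezing tolerance (23.9). The zinc finger gene ZAT12 had 59.1 at −1029 bp, outside the window. No peak was listed for RD29A, RD29B, RAB18, RD20, KIN1, COR15A, ERD10 or ICE1. COR28, a homologue of COR27 left out of the test because its symbol did not match, had 56.9 at −1227 bp and 43.8 at −54 bp.

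Of 33 ABA signalling genes, 6 had a promoter peak (18.2%, odds ratio 5.60, 95% interval 1.89 to 13.9, adjusted p = 0.00285, Fisher's exact test). They were the receptor gene PYL7 (25.05), the phosphatase genes HAI2 (65.3) and PP2CA (9.39), the kinase genes SNRK2.2 (58.9) and SNRK2.3 (14.2), and ABI5, a bZIP transcription factor that restrains germination (6.52). PYL8 and ABI3 had peaks outside the window. Of the 13 genes of ABA biosynthesis and catabolism, 0 had a peak (exact interval 0 to 24.7%, adjusted p = 1, Fisher's exact test). Differences between lists were not tested, here or for the other lists.

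Genes of light capture, chlorophyll synthesis and starch turnover were also bound. Of 21 light-harvesting genes, 8 had a promoter peak (38.1%, odds ratio 15.5, 95% interval 5.57 to 40.6, adjusted p = 1.89e-06, Fisher's exact test), from LHCB1.3, LHCA4 (108) and LHCB1.4 (105) down to LHCB2.3 (35.8), LHCB2.1 (20.8), LHCB4.2 (7.92), LHCB4.1 (6.13) and LHCA1 (4.28). All 8 were rhythmic, with phases of 0 to 5 h. With peaks above the median −log10 q alone the share was 23.8% (adjusted p = 2.02e-04, Fisher's exact test). Of 17 starch genes, 8 were bound (47.1%, odds ratio 22.5, 95% interval 7.52 to 65.7, adjusted p = 4.32e-07, Fisher's exact test). These were the phosphorylase genes PHS2 (50.2) and PHS1 (18.6), the glucan-water dikinase gene SEX1 (32.4), the debranching enzyme gene ISA3 (21.9), LSF1 (16.6), the starch synthase gene GBSS1 (13.3), the amylase gene AMY3 (8.82) and the phosphatase gene SEX4 (6.001). The phase was 21 h for GBSS1 and 8 or 10 h for the other 7.

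In chlorophyll biosynthesis 4 of 13 genes had a promoter peak (30.8%, odds ratio 11.2, 95% interval 2.51 to 40.2, adjusted p = 0.00266, Fisher's exact test): PORB, HEMA1 (13.7), CRD1 (8.83) and GUN5 (4.89). This call rested partly on weak peaks and ended when the peaks above the median −log10 q were used alone (15.4%, adjusted p = 0.0594, Fisher's exact test).

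Regulators of flowering and light signalling were bound as well. Of 14 photoperiodic flowering genes, 6 had a promoter peak (42.9%, odds ratio 18.9, 95% interval 5.40 to 62.3, adjusted p = 1.92e-05, Fisher's exact test). They were COL9 (45.1), COL1 (7.02) and COL5 (5.95) of the CONSTANS-like family, CDF1, a repressor of CONSTANS (21.7), the floral repressor FLC (19.5) and the floral integrator SOC1 (10.3). CDF5, left out of the test for the same reason as COR28, had 25.8 at −987 bp. Of 20 photoreceptor and light signalling genes, 4 were bound (20.0%, odds ratio 6.29, 95% interval 1.53 to 19.5, adjusted p = 0.0102, Fisher's exact test): the growth-promoting bHLH gene PIF4 (15.2), the cryptochrome gene CRY2 (14.1), SPA1 (7.64) and PIF7 (3.55). CRY1 and PHOT1 had peaks outside the window. The light signalling call also ended with peaks above the median alone (10.0%, adjusted p = 0.115, Fisher's exact test).

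Among hormone lists other than ABA, the Aux/IAA genes, repressors of auxin response, passed the threshold, with 5 of 29 bound (17.2%, odds ratio 5.25, 95% interval 1.56 to 14.1, adjusted p = 0.00804, Fisher's exact test). IAA4 had 50.6, and IAA1, IAA32, IAA19 and IAA27 had 8.49, 6.31, 4.85 and 3.55. With peaks above the median alone the share was 3.45% (adjusted p = 0.568, Fisher's exact test). Of 21 jasmonate genes, 3 were bound, JAZ6 (17.5) and the tandem genes AOC1 (16.3) and AOC2 (5.23), which did not pass the threshold (14.3%, odds ratio 4.19, 95% interval 0.789 to 14.4, adjusted p = 0.0650, Fisher's exact test). With the window extended to 3000 bp upstream, which added JAZ1 and JAZ3, it did (23.8%, adjusted p = 0.00461, Fisher's exact test). In the gibberellin list 1 of 17 genes, the receptor gene GID1A (17.5), had a promoter peak (adjusted p = 0.598, Fisher's exact test), and GA2OX1 (63.2 at −3106 bp) and RGA (16.3 at −5920 bp) had peaks outside the window. With every gene the authors paired with a peak the share was 17.6% (3 of 17, adjusted p = 0.0802, Fisher's exact test). In the ethylene list 0 of 23 genes had one (exact interval 0 to 14.8%), and ACO4 had a peak outside the window (12.9 at −1835 bp).

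Of 21 genes in the list of constitutive controls, 2 had a promoter peak, TUA5 (86.9) and UBQ10 (4.45), with an odds ratio of 2.64 (95% interval 0.298 to 10.98, adjusted p = 0.255, Fisher's exact test). The odds ratios of the ABA signalling, light signalling and Aux/IAA lists lie inside that interval. TUA5, a tubulin gene, was itself listed as rhythmic, with a phase of 9 h; with peaks above the median alone the share fell from 9.52% to 4.76%. Of 10 seed storage and oil body genes, 0 had a peak (exact interval 0 to 30.8%). The control library was input DNA, and no library from plants lacking LHY was analysed here.

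**Figure D2:**
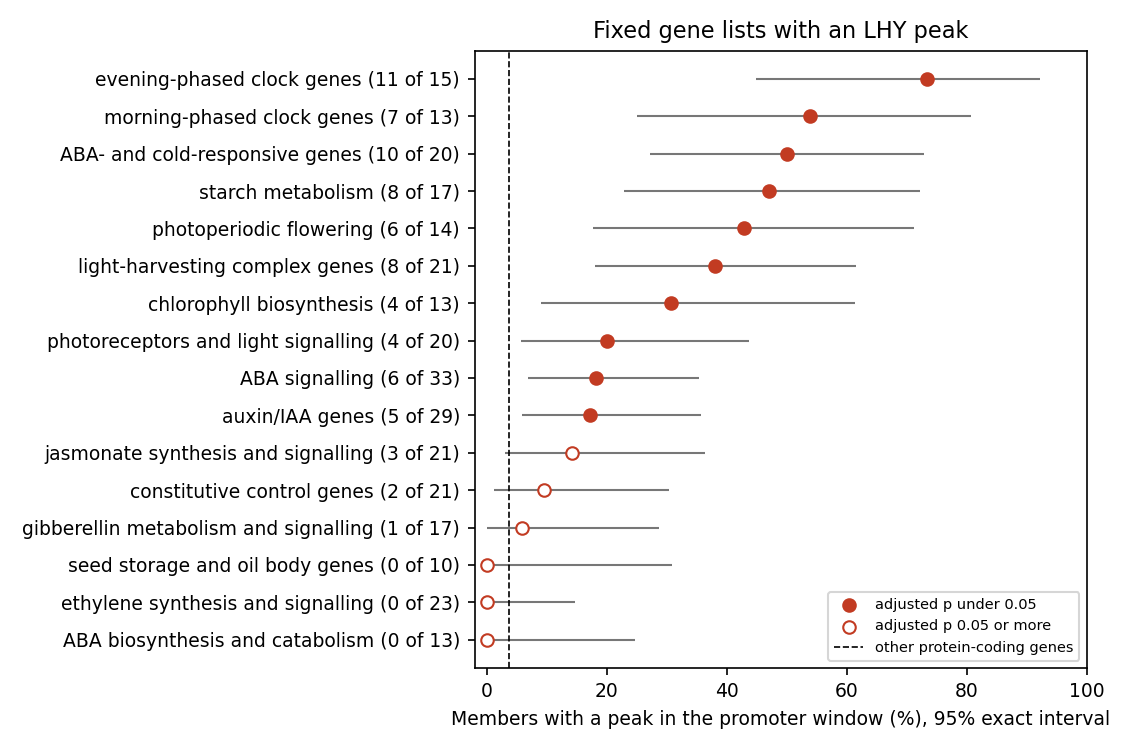
Points give the percentage of each list's members with an LHY peak in the promoter window, with 95% exact intervals, and the dashed line marks other protein-coding genes (3.8%); filled points have an adjusted p below 0.05. The 10 lists past the threshold run from the Aux/IAA genes (17.2%) to the evening-phased clock genes (73.3%).

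Genes bound by LHY peaked in expression most often in the second part of the subjective day. A phase in constant light was listed for 610 genes (38.1%, exact interval 35.7 to 40.5). Of these, 277 (45.4%, exact interval 41.4 to 49.5) peaked at 6 to 11 h, 137 (22.5%) at 0 to 5 h, 106 (17.4%) at 12 to 17 h and 90 (14.8%) at 18 to 23 h. The most frequent phase was 8 h, with 93 genes, GRP7, COR27 and PHS1 among them. FKF1, TOC1 and BOA peaked at 10 h. Phases of genes without a peak were not analysed here, so these shares were not compared with the genome.

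Genes with stronger peaks were more often rhythmic. In the strongest group, which holds FKF1, TOC1 and GI, 211 of 401 genes had a phase (52.6%, exact interval 47.6 to 57.6), against 122 of 436 (28.0%, exact interval 23.8 to 32.4) in the weakest group, which holds LHCA1, GUN5 and PIF7 (odds ratio 2.85, 95% interval 2.12 to 3.85, adjusted p = 1.63e-12, Fisher's exact test). The groups between had 30.8% and 41.8%. The coverage of each group by the phase database was not analysed here, so its part in this difference is unknown. Among genes whose strongest peak lay outside the promoter window, divided anew at their own quartiles, the odds ratio was 1.89 (95% interval 1.09 to 3.32, unadjusted p = 0.0174, Fisher's exact test). Genes with their strongest peak in the promoter window were rhythmic in 452 of 1094 cases (41.3%) and other genes in 158 of 508 (31.1%; odds ratio 1.56, 95% interval 1.24 to 1.96, adjusted p = 1.72e-04, Fisher's exact test). Promoter location was itself more frequent in the strongest group, with 73.3% against 65.1% (odds ratio 1.47, 95% interval 1.08 to 2.00, adjusted p = 0.0110, Fisher's exact test).

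Among rhythmic genes, a phase of 6 to 11 h was more frequent at stronger peaks, in 115 of 211 genes (54.5%) of the strongest group and 40 of 122 (32.8%) of the weakest (odds ratio 2.45, 95% interval 1.51 to 4.03, adjusted p = 2.13e-04, Fisher's exact test). The groups between had 31.7% and 53.5%. Mean phases, taken on the circle of hours, were 8.10 h in the strongest group and 6.40 h in the weakest. Their 95% bootstrap intervals over genes, 7.38 to 8.86 and 4.70 to 8.21, overlapped. The difference in phases of 6 to 11 h depended on the hours counted. By the same exact test, from 8 to 13 h the odds ratio was 2.03 (unadjusted p = 0.00365), but from 4 to 9 h it was 0.974 (unadjusted p = 0.909), and for genes whose strongest peak lay outside the promoter window, divided anew at their own quartiles, it was 1.84 for 6 to 11 h (unadjusted p = 0.240). Within the strongest group, genes above and below its median had this phase in 55.4% and 53.3% of cases (odds ratio 1.09, 95% interval 0.605 to 1.95, unadjusted p = 0.782, Fisher's exact test).

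**Figure D3:**
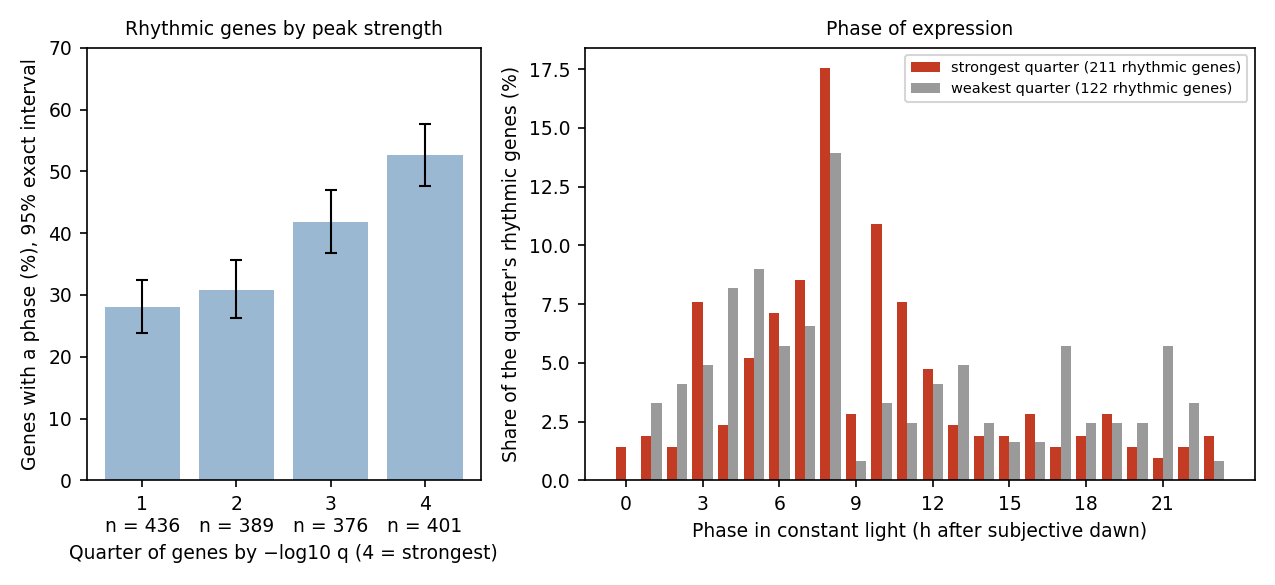
The left panel gives the percentage of genes with a phase in the 4 groups of rising −log10 q, with 95% exact intervals, from 28.0% in the weakest to 52.6% in the strongest. The right panel gives the percentage of rhythmic genes at each hour after subjective dawn in the strongest (211 genes) and weakest (122 genes) group. The bars at 10 and 11 h are taller in the strongest group. Over 4 to 9 h the shares are 43.6% in the strongest and 44.3% in the weakest group.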

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

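The alternatives for the strength, phase and position comparisons, the matching of list members by locus alone and the counting of shared peaks once were chosen after seeing the data. Of 96 alternative values for the gene lists, 90 kept their direction and side of the threshold, and 12 of the 16 lists did so under all 6 settings. Among those 12, the ABA biosynthesis and the seed storage lists had no member with any peak, so they could not change. By Fisher's exact test with peaks above the median −log10 q alone, chlorophyll biosynthesis (15.4%, adjusted p = 0.0594), light signalling (10.0%, adjusted p = 0.115) and Aux/IAA genes (3.45%, adjusted p = 0.568) no longer passed; fewer peaks enter by construction. Jasmonate genes passed with 3000 bp upstream (23.8%), with all annotated genes as background (14.3%, adjusted p = 0.0335) and with any gene the authors paired with a peak (23.8%); in the second case the share was unchanged and the background differed. The number of lists past the threshold was 7 to 11, against 10. The promoter share was 51.2% with 500 bp, 89.8% with 3000 bp and 70.2% for peaks above the median. The odds ratio for rhythmic genes at stronger peaks was 1.89 to 3.18 over its alternatives. That for a phase of 6 to 11 h was 1.84 outside the promoter window (1.76 with the groups of all genes kept) and 0.974 for 4 to 9 h; the cause was not tested.

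No paired analysis was possible because each group has 1 library. Not run, for want of coordinates, sequence, fold enrichment or pileup, were the gene body window, overlap of the whole peak, the circular shift, the peaks of highest fold, ranking by pileup and all motif alternatives. Depth is unknown, so genes absent from the list cannot be told from genes under the detection limit.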

Other observations

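Of the tests in this part, the split of the strongest group was set before its result was seen; the others were chosen after looking at the data. Biological process terms printed in the gene descriptions were compared within the list, for the 19 terms with at least 15 genes (883 genes had a term). Genes annotated to cold response had stronger peaks: 14 of 23 were in the strongest group (60.9%), against 24.9% of other annotated genes (odds ratio 4.69, 95% interval 1.86 to 12.5, adjusted p = 0.00964, Fisher's exact test). Of the genes named above, KIN2, COR15B and GRP8 were among these 14. Others included ERD7, an early dehydration-responsive gene (106 at −32 bp), the alternative oxidase gene AOX1A (88.4 at −256 bp) and BBX29 (86.8 at −494 bp). The germin gene GER3 (74.5 at −812 bp) and the plastid fibrillin gene FIB (68.9 at −446 bp) also belonged. The 23 genes are those whose printed description carries the term, and CBF1, CBF2, CBF3, CBF4, COR27, COR28 and COR47 are not among them. With a minimum of 20 genes per term, 8 terms were left and the adjusted p was 0.00812. Without the genes of the fixed lists, 11 of 18 were in the strongest group (odds ratio 4.98, 95% interval 1.74 to 15.4, unadjusted p = 9.91e-04, Fisher's exact test).

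Of 11 rhythmic genes annotated to photosynthesis, 9 had a phase of 0 to 5 h (81.8%), against 16.9% of other rhythmic annotated genes (odds ratio 21.8, 95% interval 4.37 to 212, adjusted p = 4.32e-04, Fisher's exact test). This largely restates the phases of the light-harvesting list given above, to which 7 of the 9 belong. Without the genes of the fixed lists, 2 of 3 had such a phase (odds ratio 9.34, 95% interval 0.479 to 558, unadjusted p = 0.0840, Fisher's exact test), the photosystem I genes PSAL (4 h) and PSAD-1 (3 h), while the photosystem II gene PSBP-1 had 6 h. Each term was tested 3 times, for the strongest group and for phases of 0 to 5 and 6 to 11 h, and 2 of the 57 tests passed after adjustment over all of them; the first window was kept after the second had been examined.

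The higher share of rhythmic genes at stronger peaks was weighed against 3 technical explanations. Weaker peaks may lie farther from the TSS and be paired with the wrong gene. Among genes with their strongest peak in the promoter window, divided anew at their own quartiles, the odds ratio was 3.18 (95% interval 2.21 to 4.59). It was 3.06 with the groups of all genes kept. The difference thus held without the distant peaks, but a peak in the window can still be paired with the wrong gene. Loci not annotated as protein-coding, unmatched ones included, numbered 56 in the weakest and 12 in the strongest group, yet among protein-coding genes the odds ratio was 2.56 (95% interval 1.88 to 3.49), and 2.53 with the groups of all genes kept. False calls among weak peaks should be rare in the strongest group. The genes above that group's median were still more often rhythmic than those below (60.5% against 44.8%, odds ratio 1.89, 95% interval 1.25 to 2.87). This gradient cannot tell how far false calls lower the share in the weakest group. A hypothesis left open is that LHY occupancy goes with rhythmic expression; expression level and open chromatin, which could raise both peak strength and the chance of a rhythm call, were not measured here, and the design has no group that tests a biological explanation.

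The same −log10 q recurred at many peaks: 17 values, each held by at least 9 distinct peaks, covered 464 peaks (27.1%), and 69 peaks had 6.80. A candidate explanation is that the peaks at these values rest on whole read counts over 1 constant background rate. In that case 10 to the power of the step between successive values would grow about linearly, if the values are uncorrected p-values of Poisson counts. The headers do not settle whether they are p-values or q values, and a correction would alter the steps. Values above 21.7 also recurred at fewer peaks, such as 32.3 at BZO2H3 and RABA1c, and were not tested. Over all 17 values a straight line gave an R squared of 0.177, but the minimum of 9 peaks had removed 3 values from the series (18.4, 19.5 and 20.6, held by 6, 6 and 8 peaks), so that result decides nothing. Restricted, after that result, to the 16 values before this gap, R squared was 0.999, against at most 0.478 in 1000 random draws of as many other values. Random draws have irregular steps, so this comparison cannot tell a constant background from another source of regular steps. The line, carried on through the gap, came within 0.0177 of each of the 3 values and of the next, 21.7, but both steps followed the first result and the explanation remains a hypothesis.

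Where neighbouring protein-coding genes shared a peak, the nearer gene was not found to be the rhythmic one more often. Of 46 such shared peaks, both genes were rhythmic at 9, the nearer alone at 12, the farther alone at 15 and neither at 10. The nearer gene was thus rhythmic at 44.4% of the 27 discordant peaks (95% exact interval 25.5 to 64.7, exact McNemar p = 0.701). That interval is too wide to tell which gene of a pair the peak belongs to. A pair of genes that shared more than 1 peak, such as IAA1 and IAA14, entered once per peak, although the test treats entries as independent. This rule for finding shared peaks replaced another that was tried while exploring the data, which is not reported here.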
